A study of Mus musculus with 16 samples.

How the data were processed

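Chromatin immunoprecipitation followed by sequencing (ChIP-seq) measured where RUNX1, MyoD, c-Jun and MyoG were bound in mouse muscle cells. Per the labels, satellite cells, the stem cells of skeletal muscle, came from the gastrocnemius of C57BL/6 mice aged 2 to 3 weeks. RUNX1, MyoD and c-Jun were precipitated from proliferating myoblasts after 3 days in culture, and MyoG from cells kept for 24 hours in differentiation medium. The 16 samples formed 8 groups of 2: 4 ChIP groups and 4 control groups. The controls were non-immune serum for RUNX1 and IgG for MyoD, c-Jun and MyoG. Chromatin was sheared to fragments near 300 bp, and libraries of about 250 bp were made with 15 PCR cycles, per the labels' protocols.

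The files held 4 peak lists, 1 per factor, on the mouse build mm9. CASAVA 1.7.0 and 1.8.2 and Bowtie were named in the submitters' processing notes, without a version for Bowtie. Each deposited peak carried a name that began with MACS, a peak caller, and a score that the authors' software had written. The lowest score was 50.01 in every list, and many peaks sat at exactly 3100. This value is called the score ceiling below, although some scores lay above it, up to 3233. Whether peaks above 3100 were stronger than peaks at 3100 is not known. The MACS version, its settings, the control used and whether replicates were joined before calling are not given in the sources used here. The score was used only to rank and stratify peaks within 1 list. The names of 3 lists matched the labels of RUNX1, MyoD and c-Jun, and the fourth list, under an abbreviation, was assigned to MyoG by elimination.

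No list separated the replicates, so no spread between cultures could be computed. The lists held no read counts, so the depth of each library is unknown and no counting interval was given. The control samples had no values of their own in the lists and were not analysed here. Errors are jackknife standard errors (SE) from leaving out each of 20 chromosomes in turn. They describe variation along the genome and not variation between animals, and the p-values treat positions or peaks as the units.

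Chromosomes 1 to 19 and X were used. The build was checked against chromosome lengths from GenomeInfoDb 1.38.1: 0 peaks in any list lay beyond an mm9 chromosome end, and between 328 and 550 peaks per list lay beyond an end of the later build mm10. Peaks were counted as shared if they overlapped by at least 1 bp. The observed number was divided by the mean of 1000 circular shifts of 1 list along each chromosome, with a one-sided p whose smallest value is 0.001. The 6 pairs of lists were adjusted together by the Benjamini-Hochberg method. Odds ratios were tested with the two-sided Fisher's exact test, adjusted over 3 tests, and stratified with the Mantel-Haenszel estimator. Scores of 2 classes of RUNX1 peaks were compared by a two-sided permutation test of the rank sum with 100000 permutations. Regions were made by merging overlapping RUNX1, MyoD and c-Jun peaks. Scripts used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

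The shift test was run on 20 simulated, independent pairs of lists of the sizes of the RUNX1 and MyoD lists. Peaks were placed uniformly on each chromosome. The mean fold was 0.991, with a range from 0.926 to 1.03, and 0 pairs had p under 0.05. Uniform lists lack the regional density of real peaks, so they do not show how the test behaves for clustered lists. In 20 simulated sets with as many peaks as the MyoD list, both partners followed only a simulated strength, drawn uniformly and without the ties of the real score. The mean unstratified log2 odds ratio was 0.76 and the mean stratified one 0.01. With a planted log2 odds ratio of 2, the stratified mean was 2.01. The strata were cut from the same value that set the partners, so a score that tracks strength imperfectly was not tested.

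The tests, the main overlap rule, most alternatives and the rule for named regions were fixed before the data were examined. Alternatives were a shared span of at least 50% of the shorter peak, centres within 150 bp, the stronger 50% of each list, local shifts of 10 to 100 kb, autosomes alone, windows of 200 bp around each centre, and strata of the score in 5 classes. Strata of 10 score classes, the removal of a long MyoD stretch, the removal of peaks at the score ceiling and the widest 1%, the weaker 50% of each list, and peak classes with no other myoblast factor were added afterwards. The rule named the 10 regions bound by RUNX1, MyoD and c-Jun with the best worst rank over the lists. It also named the 5 highest-scoring RUNX1 peaks with neither MyoD nor c-Jun. Further, it named the 5 windows of 100 kb with the most regions bound by all 3 factors. Last, it named the 3 MyoG-only and 3 MyoD-only peaks of highest score. These were taken as MyoG peaks without MyoD and MyoD peaks without MyoG, whether or not RUNX1 or c-Jun was present. Genes, motifs and distances to promoters were not analysed here, since the gene table used is of another build (GRCm38.p6) and no genome sequence was used. Regions are therefore named by mm9 coordinates, counted from 1.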

Results

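The study asked where the transcription factor RUNX1 binds in primary mouse myoblasts relative to MyoD and c-Jun. MyoD is a basic helix-loop-helix factor that specifies the muscle lineage, and c-Jun is a subunit of the AP-1 factor. MyoG, a related helix-loop-helix factor that acts in muscle differentiation, was mapped in early myotubes. Each factor had 2 ChIP libraries and 2 control libraries, 16 samples in all, and the deposited result was 1 peak list per factor. The lists held 42781 RUNX1 peaks, 45951 MyoD peaks, 42134 c-Jun peaks and 62456 MyoG peaks. Median peak widths were 944 bp for RUNX1, 817 bp for MyoD, 1123 bp for c-Jun and 640 bp for MyoG, and each list covered between 1.46% and 1.89% of the chromosomes. Read depth is unknown, replicates were not separable, and differences in peak number between factors were therefore not compared. The list taken as MyoG was assigned by elimination.

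In proliferating myoblasts, a large part of the RUNX1, MyoD and c-Jun peaks overlapped by at least 1 bp. A MyoD peak overlapped 44.3% ± 0.343 (SE over 20 chromosomes, as below) of the RUNX1 peaks, and a c-Jun peak overlapped 46.8% ± 0.395. In the other direction, 42.5% ± 0.851 of MyoD peaks and 46.8% ± 0.987 of c-Jun peaks met a RUNX1 peak. MyoD and c-Jun shared sites to a similar extent, with c-Jun at 41.9% ± 0.361 of MyoD peaks. Shifted positions gave 3.51%, 3.8% and 3.37% for these pairs.

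The overlap was 12.6 ± 0.543 times the shifted mean for RUNX1 with MyoD, 12.3 ± 0.458 times for RUNX1 with c-Jun and 12.4 ± 0.4 times for MyoD with c-Jun. Each pair reached a permutation p = 0.001 over circular shifts, the smallest value that 1000 shifts can give (adjusted p = 0.001 over 6 pairs), and each lay above the shifted mean on 20 of 20 chromosomes. Among overlapping peaks, the centres lay a median of 123 bp ± 2.85 apart for RUNX1 and MyoD, 138 bp ± 2.96 for RUNX1 and c-Jun and 116 bp ± 2.17 for MyoD and c-Jun. Overlaps of peaks moved by 20 local shifts of 10 to 100 kb had medians of 482 bp, 579 bp and 509 bp. The size of the fold depended on the reference positions and on the overlap rule. Local shifts of 10 to 100 kb lowered the folds to 5.72 ± 0.149, 5.78 ± 0.126 and 6.04 ± 0.0937 in the same order. Requiring centres within 150 bp raised them to 44.8, 48.3 and 48.0, since overlaps of shifted positions fell more steeply than observed ones. That rule lowered the overlapped peaks from 18959 to 10696, from 20005 to 10537 and from 19232 to 11154.

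**Figure D1:**
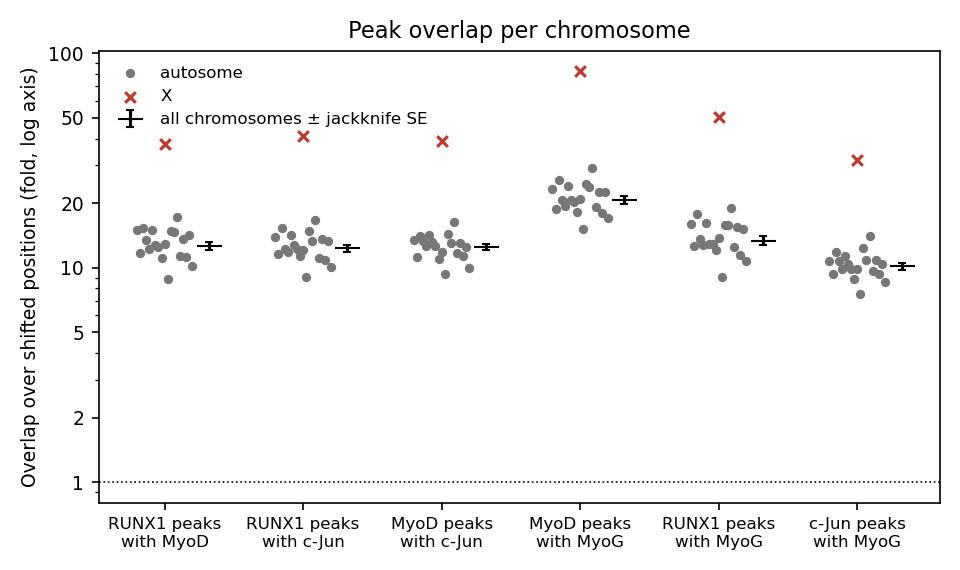
Overlap of each pair of peak lists divided by the mean of shifted positions, on a log axis: grey points are the 19 autosomes, red crosses chromosome X, and black bars the value over all chromosomes ± jackknife SE. Every chromosome lay above 1 for the 6 pairs, and X, where peaks were sparse, had the highest folds, from 31.6 for c-Jun with MyoG to 82.3 for MyoD with MyoG.

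The 3 myoblast factors also met at the same sites. A c-Jun peak was present at 61.3% ± 0.409 of the RUNX1 peaks that MyoD shared (11629 of 18959) and at 35.2% ± 0.426 of those without MyoD (8376 of 23822). RUNX1 peaks fell into 11629 with both other factors (27.2%), 7330 with MyoD alone (17.1%), 8376 with c-Jun alone (19.6%) and 15446 with neither (36.1%). The log2 odds ratio of c-Jun with against without MyoD was 1.55 ± 0.028, above 0 on 20 of 20 chromosomes. Its two-sided Fisher's exact p lay below the smallest number that could be stored, 2.2e-308 (adjusted p below 3.3e-308 over 3 tests). The number of RUNX1 peaks that met both factors depended on the rule and was 4355 with centres within 150 bp.

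RUNX1 peaks that met both factors were also stronger. Their median score was 307.7, against 117.5 for RUNX1 peaks with neither factor, on the authors' scale. A RUNX1 peak with both factors outranked one with neither with a probability of 0.711 ± 0.00436 (permutation p = 1e-05, the smallest that 100000 permutations can give). With centres within 150 bp the probability was 0.616 ± 0.00463. With MyoD alone the median score was 160.4, and with c-Jun alone it was 227.4.

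Merging the 3 myoblast lists gave 83179 regions, of which 11533 (13.9% ± 0.247) held RUNX1, MyoD and c-Jun. The 10 such regions with the best worst rank included 6 in which each of the 3 factors was at or above the score ceiling of 3100. These lay on chromosome 18 from 14488489 to 14490914, chromosome 2 from 13330927 to 13333347, chromosome 6 from 91566266 to 91572104, chromosome 7 from 30791107 to 30796397, chromosome 10 from 79621183 to 79629259 and chromosome 15 from 28060949 to 28064533. The ceiling leaves these 6 without an order. The other 4 lay on chromosome 10 from 128356027 to 128361691, chromosome 19 from 5836524 to 5850927, chromosome 1 from 78533576 to 78536581 and chromosome 9 from 49470610 to 49472778, with c-Jun scores from 2436 to 2962. Each of the 10 regions also held a MyoG peak of myotubes, with scores from 1429 to 3100. Of the 10, 4 still held a RUNX1 peak met by both factors when centres had to lie within 150 bp.

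Some windows of 100 kb held several regions bound by all 3 factors. No reference count from peak density was computed, so whether such regions grouped beyond it was not tested. Among 6677 windows of 100 kb with at least 1 such region, the median was 1 and 229 windows held 5 or more. The window on chromosome 2 from 60500001 to 60600000 held 11, along with 14 RUNX1, 18 MyoD, 11 c-Jun and 18 MyoG peaks. Those on chromosome 4 from 154500001 to 154600000, chromosome 8 from 13600001 to 13700000, chromosome 16 from 92900001 to 93000000 and chromosome 17 from 26700001 to 26800000 held 9 each. The 5 highest-scoring RUNX1 peaks with neither MyoD nor c-Jun had scores from 3141 to 3222, above the score ceiling. They lay on chromosome 1 from 167563854 to 167565207, from 152894615 to 152895891 and from 158648197 to 158649676, on chromosome 19 from 36810629 to 36811654 and on chromosome 4 from 108520151 to 108521597. Of these 5, the peak on chromosome 19 met a MyoG peak, with a MyoG score of 97.96. In the whole RUNX1 list, 364 peaks sat at exactly 3100, and whether the 5 were stronger than those is not known.

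Most MyoD sites of myoblasts were MyoG sites of myotubes. A MyoG peak overlapped 77.1% ± 0.608 of MyoD peaks (35429 of 45932), against 3.72% for shifted positions. The centres of these overlapping peaks lay a median of 53 bp ± 1.31 apart, and 87.6% lay within 150 bp. In the other direction, 57.7% ± 0.395 of MyoG peaks met a MyoD peak. RUNX1 and c-Jun peaks met MyoG less often than MyoD peaks did, at 57.9% ± 0.340 and 45.1% ± 0.728.

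The folds over shifted positions were 20.7 ± 0.822 for MyoD with MyoG, 13.4 ± 0.647 for RUNX1 with MyoG and 10.1 ± 0.343 for c-Jun with MyoG, each with a permutation p = 0.001 over circular shifts (adjusted p = 0.001 over 6 pairs) and above the shifted mean on 20 of 20 chromosomes. Local shifts lowered these folds to 9.27 ± 0.235, 5.6 ± 0.180 and 4.81 ± 0.0811, and centres within 150 bp raised them to 89.2, 46.9 and 35.6. The centre rule lowered the overlapped peaks from 35429 to 31045, from 24775 to 15396 and from 19017 to 11324. Factor and cell stage differed together here, so the 2 cannot be separated.

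Among MyoD peaks, those shared with RUNX1 in myoblasts nearly always had a MyoG peak in myotubes. The share was 91.7% ± 0.267 with RUNX1 (17893 of 19505) and 66.4% ± 0.565 without it (17536 of 26427). For c-Jun the difference was smaller, 82.2% ± 0.552 with c-Jun (15813 of 19232) and 73.5% ± 0.693 without it (19616 of 26700). With c-Jun but not RUNX1 the share was 67.9% ± 0.733, close to the 65.7% ± 0.608 of MyoD peaks with neither factor. The peaks with c-Jun alone were the stronger ones. At a matched MyoD score, their share was lower than with neither in 8 of 10 score classes and higher in 2. In the weakest class it was 38.4% ± 2.31 with c-Jun alone and 46.1% ± 1.04 with neither. Over all scores, the share with RUNX1 but not c-Jun was 92.3% ± 0.330, and with both 91.4% ± 0.289. These last shares were close although MyoD peaks with both were stronger, and at a matched MyoD score the share was lower with both in 9 of 10 score classes. The gap was widest in the weakest class, at 61.9% ± 3.48 with both and 79.8% ± 1.67 with RUNX1 alone. It closed towards strong MyoD peaks, with 98.4% ± 0.284 against 97.7% ± 0.603 in class 9 and 99.6% ± 0.0923 against 99.6% ± 0.269 in class 10. Both shares were near their upper limit there, so a gap in percent had to be small whatever the odds ratio.

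The log2 odds ratio was 2.49 ± 0.027 for RUNX1 (Fisher's exact p below 2.2e-308, adjusted p below 3.3e-308) and 0.74 ± 0.031 for c-Jun (Fisher's exact p = 1.131e-109, adjusted p = 1.131e-109), each above 0 on 20 of 20 chromosomes. MyoD peaks with a partner were stronger, with median scores of 193.3 with RUNX1 alone, 212.7 with c-Jun alone, 442.8 with both and 114.2 with neither. Stratified into 5 classes of the MyoD score, the RUNX1 value was 1.98 ± 0.032 and the c-Jun value turned to -0.070 ± 0.036. Stratified by the presence of RUNX1, the c-Jun value was 0.07 ± 0.033. In 10 score classes, the RUNX1 value was 1.96 ± 0.030 and the c-Jun value -0.10 ± 0.036, a difference of 2.06 ± 0.037 that lay above 0 on 20 of 20 chromosomes. Stratified by score class and by the other partner together, the RUNX1 value was 2.16 ± 0.033 and the c-Jun value -0.61 ± 0.037, a negative association.

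**Figure D2:**
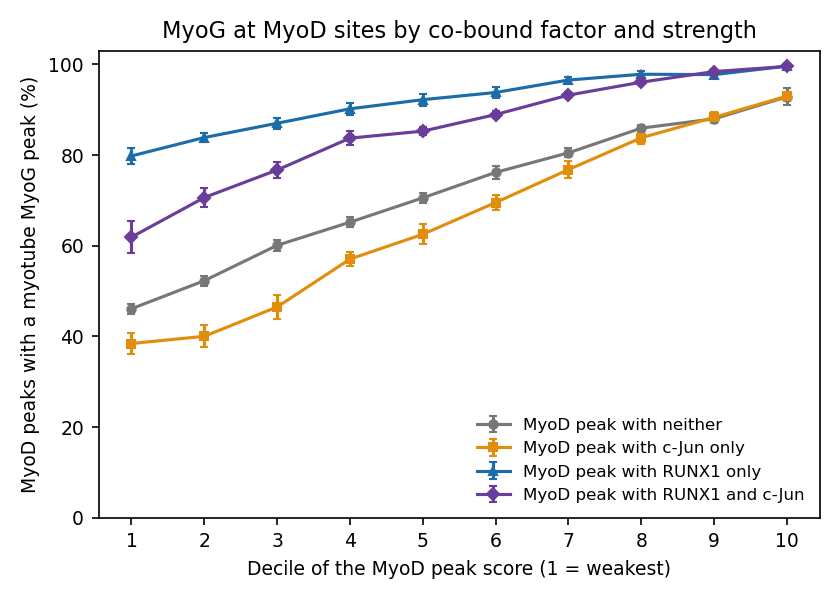
Percent of myoblast MyoD peaks with a myotube MyoG peak (vertical axis) in 10 equal classes of the MyoD score, from weakest (1) to strongest (10), for MyoD peaks with neither partner (grey), c-Jun alone (orange), RUNX1 alone (blue) and both (purple), ± jackknife SE. Peaks with RUNX1 alone lay above peaks with neither in 10 of 10 score classes, peaks with c-Jun alone lay below peaks with neither in 8 of 10, and peaks with both lay below those with RUNX1 alone in 9 of 10.

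The same order held over merged myoblast regions. A MyoG peak was present in 93.2% ± 0.362 of regions with RUNX1 and MyoD, in 91.9% ± 0.334 with all 3 factors, in 68.2% ± 0.741 with MyoD and c-Jun and in 65.7% ± 0.608 with MyoD alone. Regions without MyoD had fewer: 33.6% ± 0.671 with RUNX1 and c-Jun, 30.2% ± 0.483 with RUNX1 alone and 7.26% ± 0.312 with c-Jun alone.

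**Figure D3:**
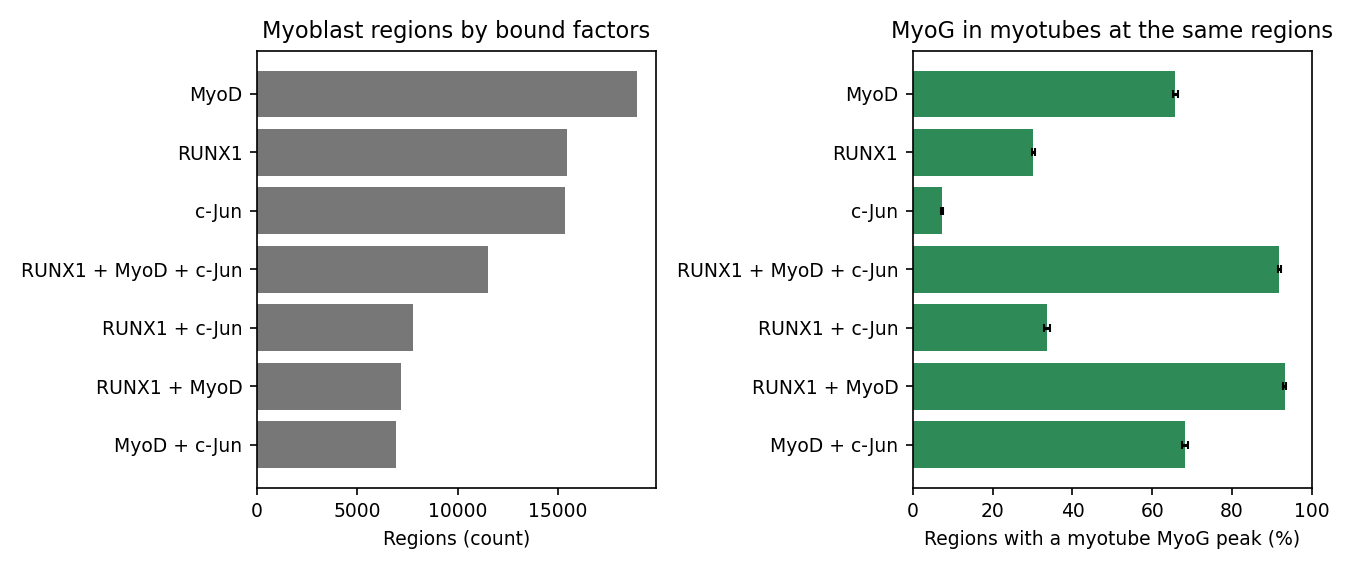
Merged myoblast regions by the factors that bound them: the number of regions (left, grey bars) and the percent with a MyoG peak of myotubes (right, green bars, ± jackknife SE). Regions with MyoD alone were the most numerous class (18934), and the percent with MyoG ran from 7.26% with c-Jun alone to 93.2% with RUNX1 and MyoD.

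Some high-scoring MyoG peaks had no MyoD peak in myoblasts, and some high-scoring MyoD peaks had no MyoG peak in myotubes. The 3 highest MyoG peaks without a MyoD peak lay on chromosome 2 from 152897399 to 152898278, on chromosome 19 from 7130697 to 7131816 and on chromosome 7 from 139912008 to 139913047, with scores from 2237 to 2499. The first and the second of these met a RUNX1 peak in myoblasts, with RUNX1 scores of 1489 and 838.2, and the second also met a c-Jun peak with a score of 162.6. The MyoD peak without MyoG with the highest score, 3224, lay on chromosome 11 from 81984865 to 81985860. It met a RUNX1 peak with a score of 62.27 and a c-Jun peak with a score of 67.42. The next pair had scores of exactly 3100, the score ceiling, so these 3 peaks are without an order. In the whole MyoD list, 807 peaks sat at exactly 3100, and the number of those without MyoG is not given. The pair may thus be a choice among ties. That pair, from 77785213 to 77790084 and from 77808388 to 77815703 on chromosome 2, lay inside a stretch of 163 kb of which MyoD peaks covered 77.9%. This stretch was singled out after its values were seen.

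**Figure D4:**
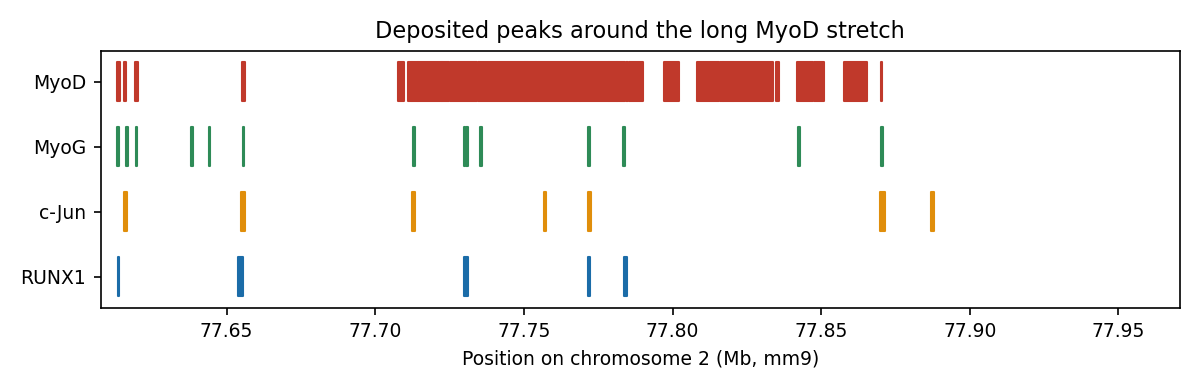
Deposited peaks (bars drawn to scale) of the 4 lists along chromosome 2 (mm9 position in Mb) around the stretch from 77707619 to 77870638. MyoD peaks covered 77.9% of the stretch, while MyoG, c-Jun and RUNX1 peaks covered 2.86%, 2.37% and 1.99%.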

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

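All tests in this part were chosen after the result was seen. The MyoD list held 19 peaks on chromosome Y, which no comparison used, and the other 3 lists held 0 there. These peaks lay between 1266407 and 2901320, 7 of them were wider than 4 kb, 7 were at the score ceiling, and together they covered 78.7 kb. The stretch of chromosome 2 from 77707619 to 77870638 also held wide MyoD peaks, 28 in all and 11 of them wider than 4 kb, in a denser run than on Y, and elsewhere on chromosomes 1 to 19 and X the MyoD list held 2 peaks of that width.

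Broad binding at a highly occupied locus would show in other lists, but the highest cover of the chromosome 2 stretch by another list was 2.86%, which argues against broad binding shared between factors there; broad binding of MyoD alone was not tested. Repeated DNA, or DNA in extra copies in the cells behind the MyoD libraries, stays open as a hypothesis: the stretch was bounded by its MyoD peaks, so their cover of 77.9% restates the pattern and does not test it, and copy number was not measured. A larger share of male cells behind the MyoD libraries could bear on chromosome Y and would lower the X to autosome ratio of peak density, but that ratio was highest in the MyoD list, at 0.240 against 0.234 for c-Jun and 0.233 for MyoG (Fisher's exact adjusted p = 0.774 for each) and 0.195 for RUNX1 (adjusted p = 0.001535). It still cannot be told apart from other causes, since the RUNX1 and c-Jun lists, both without peaks on Y, differed as well (adjusted p = 0.003502 by Fisher's exact test) for reasons that were not tested.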

How the results depend on the processing

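The removal of the long MyoD stretch, the removal of peaks at the score ceiling and the widest 1%, the weaker 50% of each list, strata by the presence of a partner, and the folds of peaks with no other myoblast factor were chosen after the result was seen. Of 81 alternatives to the results that answer a comparison, 77 kept the direction and the side of the threshold (for odds ratios, a 95% jackknife interval without 0), or a count within 1.5 times, and 4 did not. Among the 77, the log2 odds ratio of MyoG at MyoD peaks with against without c-Jun stayed above 0 but fell from 0.74 to 0.07 ± 0.033, about 2 SE above 0, when stratified by RUNX1. The 48 alternative folds of list pairs all stayed above 1 with a permutation p = 0.001 from circular or local shifts, the smallest possible, between 4.81 and 89.2. These include the removal of the long MyoD stretch for pairs without the MyoD list. It could not change their overlap, so it adds no support there. The c-Jun log2 odds ratio reversed to -0.070 ± 0.036 in 5 score classes, within 2 SE of 0. Stronger MyoD peaks more often had c-Jun and MyoG. Strata of 10 score classes, added afterwards, are not among the 81 alternatives. They put the c-Jun value further below 0, at -0.10 ± 0.036 (95% interval -0.17 to -0.03). Split by RUNX1 as well, the c-Jun value was -0.61 ± 0.037 (95% interval -0.68 to -0.54). The RUNX1 value stayed above 0 in these score classes, at 1.96 ± 0.030, and at 2.16 ± 0.033 when split by c-Jun as well. The number of RUNX1 peaks that met both MyoD and c-Jun fell from 11629 to 4355 with centres within 150 bp, 5613 with windows of 200 bp and 4327 in the stronger 50% of each list, which by construction hold fewer overlaps. No paired analysis was possible because the lists carry no replicate, and leaving out a replicate or using it as a block was not run for the same reason. Promoter shares, motifs and gene lists, with their alternatives, were not run without an annotation or sequence of the files' build. Library depth is unknown, so a missing peak in 1 list does not show that the factor was absent.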

Other observations

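The folds of peaks with no other myoblast factor, those without ceiling and widest peaks and those of the weaker 50% of each list were chosen after the result was seen. Myoblast peaks that met no peak of the other myoblast lists differed by factor in how often they carried MyoG in myotubes. Binding by the other factors too weak to be called as a peak was not excluded at these sites. MyoG was present at 30.2% of RUNX1 peaks, 7.26% of c-Jun peaks and 65.7% of MyoD peaks that met neither other list. Nearby shifted positions free of the other lists gave 3.52%, 2.10% and 3.35%. The folds were 8.59 ± 0.381 for RUNX1, 3.46 ± 0.104 for c-Jun and 19.6 ± 0.524 for MyoD, each with a permutation p = 0.001, the smallest that 1000 shifts can give, and above 1 on 20 of 20 chromosomes. The RUNX1 fold exceeded the c-Jun fold by 1.31 ± 0.084 on the log2 scale, with the same direction on 20 of 20 chromosomes. Shifts anywhere on the chromosome raised the folds to 20.3, 6.08 and 39.7, and centres within 150 bp raised them to 29.2, 10.5 and 82.6. The centre rule lowered the peaks with MyoG from 4670 to 2873, from 1115 to 597 and from 12447 to 11458.

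MyoG peaks with no myoblast peak numbered 16592 (26.6% ± 0.265 of the list). A RUNX1 peak was present at 31.9% ± 0.507 of MyoG peaks without MyoD and at 50.05% ± 0.760 of those with MyoD. For c-Jun the shares were 16.6% ± 0.304 and 44.6% ± 0.350.

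RUNX1 and c-Jun went differently with MyoG, and one technical explanation is that stronger peaks are called in more lists. In 10 classes of the MyoD score, the log2 odds ratio of RUNX1 with MyoG was 1.96 ± 0.030, against 2.49 unstratified. This argues against strength, as far as the MyoD score measures it, as the whole cause of the RUNX1 part. For c-Jun it was -0.10 ± 0.036 (95% interval -0.17 to -0.03) against 0.74, so MyoD strength may account for the positive c-Jun excess. Strata by the presence of RUNX1, without the score, gave 0.07 ± 0.033 for c-Jun. Co-occurrence with RUNX1 may thus account for most of the excess as well, and these explanations were not told apart. Stratifying by MyoD score leaves a negative c-Jun remainder, which was -0.61 ± 0.037 (95% interval -0.68 to -0.54) in score classes split by RUNX1 as well. The cause of this remainder was not tested. Among c-Jun peaks without MyoD, MyoG was present at 32.3% ± 0.714 with RUNX1 and 7.26% ± 0.312 without it. The log2 odds ratio was 2.61 ± 0.066, and 2.59 ± 0.070 in 10 classes of the c-Jun score. This argues against c-Jun strength there, as far as the c-Jun score measures it. MyoD binding too weak to be called as a peak was not excluded at these sites. These values show that RUNX1 and MyoG peaks co-occur across stages; whether RUNX1 has a part in later MyoG binding and whether accessible chromatin favours both were not tested and stay open.

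The overlap of RUNX1, MyoD and c-Jun was weighed in the same way. Regional peak density is argued against as the whole cause, since the lowest of the 3 folds over local shifts was 5.72 (permutation p = 0.001). A small class of high-scoring regions is argued against as the whole cause as well. The lowest fold was 8.79 (permutation p = 0.001) in the weaker 50% of each list by score. That fold was over shifts anywhere on the chromosome, so it also holds regional peak density, and local shifts were not run for the weaker 50%. The value of 12.1 without ceiling and widest peaks decides nothing, since too few peaks were left out. Shared binding of the 3 factors is a possible explanation, but recovery of accessible chromatin by any antibody was not tested and stays open.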
